A study of Caenorhabditis elegans with 4 samples.

How the data were processed

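Small RNAs of Caenorhabditis elegans were sequenced from adult males of the fog-2(q71) strain, from males that also carried alg-3(tm1155) and alg-4(ok1041), and from spermatids purified from fem-3(q20) animals. The fog-2 mutation removes sperm from hermaphrodites, so that the strain is kept as males and females. ALG-3 and ALG-4 are Argonaute proteins of the male germline. Per the labels, males were grown at 20 °C for about 60 h and were over 95% pure, while the spermatid strain was grown at 25 °C for 45 to 50 h, so that spermatids and males differ in growth temperature and time as well as in genotype and tissue. RNA was cut from a gel between standards of 18 and 26 nt and treated with tobacco acid pyrophosphatase, which lets 5' triphosphate RNAs such as 22G-RNAs be ligated.

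The deposited tables held one value per genome match of each distinct sequence. The unit was a signal made by the authors, the reads of the sequence divided by the number of its genome matches, with no scaling for library size. This was checked on every line of the files, as was the number of lines per sequence. The authors' alignment tools, their versions and the genome build were not stated. Of the 4 labelled samples, the 2 fog-2 male parts had identical values and were used as 1 library, which left 1 library per group. The mutant sample carried conflicting labels: its description and the series design named mutant males, while its source name and antibody tag named a CSR-1 immunoprecipitate. It was grouped by its description, as mutant males.

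The files gave no sequences. Sequence identifiers rose in alphabetical order, and the rank of the sequence starting at a position was compared with that of the sequence starting 1 nt further on, which separated 4 ordered bands for A, C, G and T. On simulated sequences this gave the right first base for 99.989% of 54374. The base called at 5' positions shared between libraries was the same at 99.9947% or more of them.

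The reference annotation at hand was of another build. On chromosome IV, 21-nt reads lay 10 to 43 nt before annotated piRNA starts, and this shift changed along the chromosome: of 14714 piRNAs, 9 matched at a shift of 0 and 7931 at the best shift. Coordinates were not converted. Genes, miRNAs and annotated piRNAs were therefore not assigned, and the 18 gene lists and the named genes fixed before the data were examined, alg-3 and alg-4 among them, could not be evaluated. Strand-specific 1-kb windows of 5' ends, in the coordinates of the files, took the place of genes.

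A 26G-RNA was a read of 26 nt starting with G, a 22G-RNA a read of 21 to 23 nt starting with G, and a 21U-RNA a read of 21 nt starting with U. Matches spanning more than 40 nt crossed exon junctions, and their read lengths are unknown, so that they entered only the library totals and a count of their own. Levels were scaled to all genome-matched reads of the library, since no annotation allowed structural RNA to be removed. Sequences with several matches were shared equally among them. Abundant non-G ends were 5' positions outside the end of chromosome I and the mitochondrial genome with at least 1000 reads of 20 to 25 nt that did not start with G in any library, and their share counted reads of 18 to 27 nt; they stand in for miRNAs, which could not be named. Scaling to abundant non-G ends used those with at least 1000 reads in both male libraries, a choice that favours species of males over those of spermatids. The end of chromosome I was the last 17 kb listed there.

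Windows were compared where the higher library held at least 25 reads, with the lower value not below a floor of 3 reads, and counted at 4-fold. For 26G reads the windows compared were, unless said otherwise, those with at least 25 reads in fog-2 males. That choice favours lower values in the other libraries. The windows named were fixed by rule: the 12 with most 26G reads in fog-2 males, the 6 with most in spermatids, and the 8 lowest and 8 highest in 22G reads in each comparison with at least 100 reads in the higher library. On simulated data with 200 of 4101 windows altered 8-fold, 94% were called in the right direction and 1 unaltered window was called. With 2-fold alterations, below the 4-fold bound, no window was called. The simulation held Poisson counting noise only, in windows with a mean of at least 25 reads. It is no guide to other differences between single libraries. A median was set against 10000 random lists of windows matched on level.

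No test across libraries was possible with 1 library per group. Shares are given with exact Clopper-Pearson 95% intervals and ratios with exact conditional binomial 95% intervals. The reads carried no molecular identifiers, so that PCR copies are not independent molecules and the intervals of shares and ratios and the floors cover counting error only. The fog-2 male library held 2625991 reads, the mutant library 2414532 and the spermatid library 3099865; a floor of 3 reads was 0.000114%, 0.000124% and 0.0000968% of them. Scaling, read minimum, fold, window length, the definitions of the classes and the use of sequences with single matches were varied. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.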

Results

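Small RNAs between 18 and 26 nt were profiled in 3 libraries, 1 each of fog-2 males, of males also lacking the Argonautes ALG-3 and ALG-4, and of purified spermatids. The libraries held 2625991, 2414532 and 3099865 genome-matched reads from 544611, 525128 and 905845 distinct sequences. With 1 library per group no difference has a replicate check, and "higher" and "lower" below describe these libraries only. Positions are in the coordinates of the files, whose build is not stated, and genes were not assigned.

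The first question was what the loss of ALG-3 and ALG-4 does to 26G-RNAs, the class that begins with G and is made on mRNA templates in the germline. In fog-2 males 26G-RNAs made up 2.09% of reads (95% interval 2.08 to 2.11%, 55001 reads). In mutant males they made up 0.272% (0.266 to 0.279%, 6570 reads), a 7.70-fold lower level (ratio 0.130, 0.127 to 0.133). Reads of 26 nt starting with another base were not lower: they took 0.352% of reads in fog-2 males and 0.451% in mutant males. The share of 26-nt reads that began with G was 85.6% in fog-2 males and 37.6% in mutant males. The 26G counts include reads at the end of chromosome I. There the plus-strand window 15065001 to 15066000 held 153 in fog-2 males and 363.5 in mutant males. The 26G ratio of chromosome I was 0.221, against 0.0766 to 0.124 on the other autosomes.

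**Figure D1:**
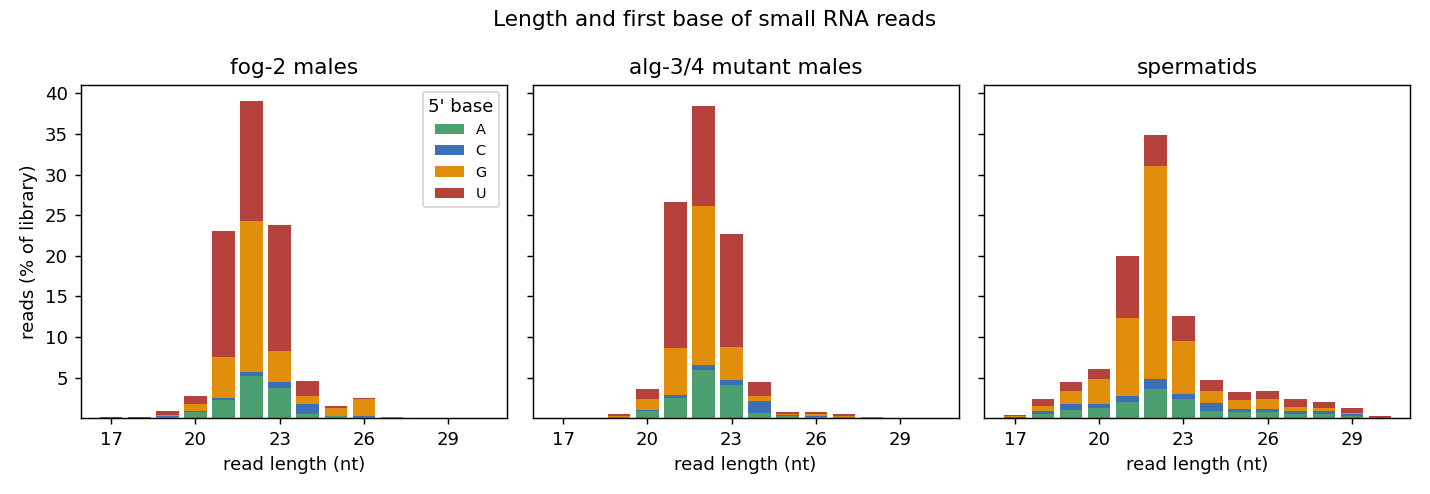
Reads by length (x axis, nt) and first base (colours) as a percent of each library (y axis). The G reads at 26 nt that stand out in fog-2 males (2.09%) are 0.272% in mutant males, and the spermatid library holds more G reads of 22 nt and more reads of 27 nt and longer (5.85%).

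The loss reached nearly all windows rich in 26G-RNAs outside the end of chromosome I. Of 592 windows with at least 25 26G reads in fog-2 males, 565 were at least 4-fold lower in mutant males and 0 were at least 4-fold higher. These 592 windows held 55.9% of the 26G reads of fog-2 males. The remaining 27 included all 11 windows at the end of chromosome I, where ribosomal RNA genes lie. In 199 of the 592 windows no 26G read was found in the mutant library, and 484 held 3 or fewer. The windows lay on all autosomes, 129 on I, 105 on II, 105 on III, 151 on IV and 101 on V, but only 1 lay on X. Chromosome X spans 17.7% of the listed nuclear length and held 0.585% of 26G reads in fog-2 males. Its few 26G reads were not clearly lower in mutant males, at 321 and 282 reads (ratio 0.953, 0.811 to 1.12).

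The 12 windows with most 26G reads in fog-2 males were all at least 4-fold lower in mutant males. The window 5014001 to 5015000 on the minus strand of II held 390 reads in fog-2 males and 10 in mutant males, 35.9-fold lower (19.3 to 75.4). Further along that strand, 11906001 to 11907000 held 330 and 2 reads, a 101-fold difference at a floor of 3 reads. The interval from the counts themselves was wide (41.7 to 1258). On chromosome III, the plus-strand window 9385001 to 9386000 held 212 and 4.5 reads, 43.3-fold lower. The smallest difference of the 12 was on the plus strand of II, 14804001 to 14805000, with 242 and 27 reads (8.24-fold lower, 5.53 to 12.8). Of the 12 windows, 2 on the minus strand of V, starting at 14884001 and 14890001, rested on sequences with several matches (0.567% and 0.336% of their reads had a single match).

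A small group of 26G loci was not lower by 4-fold. Of the 581 windows outside the end of chromosome I with at least 25 reads in fog-2 males, 565 were at least 4-fold lower. Some of the rest held fewer than 25 26G reads in mutant males and are counted among the 573 other windows below. Outside the end of chromosome I, 9 windows held at least 25 26G reads in mutant males and were not 4-fold lower, 2 on II, 1 on III, 2 on IV and 4 on V. Together they held 506 26G reads in fog-2 males, 544 in mutant males and 32 in spermatids. Of these 9, here called kept, the window 14826001 to 14827000 on the plus strand of V was 2.81-fold lower (1.87 to 4.34), with 98.3 and 32.2 reads, and its 22G reads were 8.74-fold lower. The summed 26G level of the 9 in mutant males was 1.17 times that in fog-2 males (1.03 to 1.32), and in spermatids it was 18.4-fold lower than in fog-2 males (13.1 to 27.6) as a share of all reads and 0.428 times it (0.286 to 0.604) relative to abundant non-G ends. In the 573 other 26G windows outside the end of chromosome I, the level was 25.5-fold lower in mutant males (23.96 to 27.1) and 2.64-fold lower in spermatids (2.59 to 2.70), and 2.98 times the fog-2 male level relative to abundant non-G ends. The 9 windows were chosen for what they held in the mutant library, so the mutant values are not independent of the choice. The spermatid values played no part in it.

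**Figure D2:**
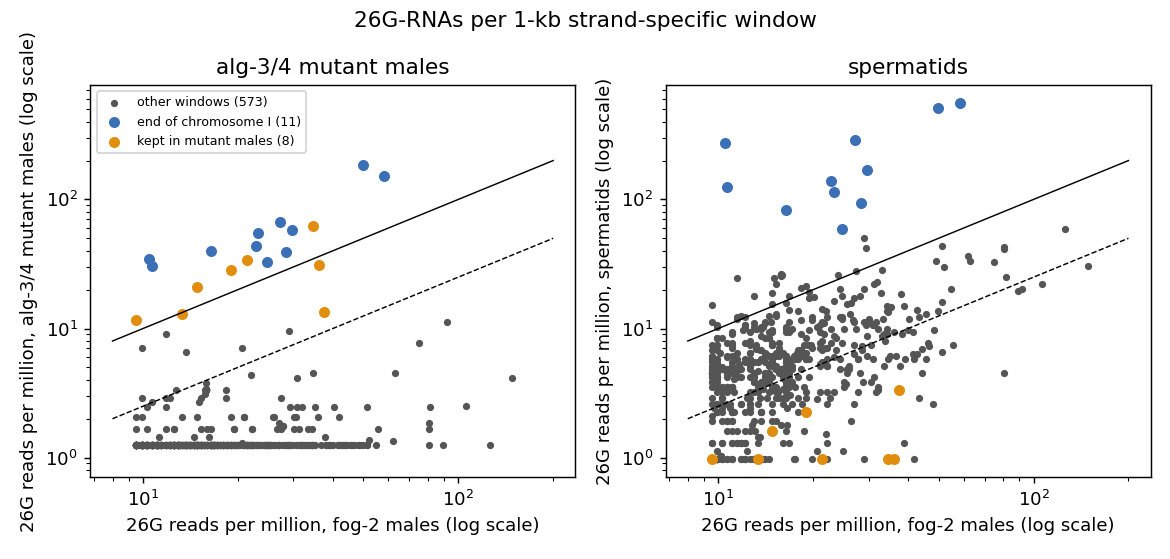
26G reads in fog-2 males (x axis, scaled to library reads) against mutant males (left) and spermatids (right), both on log scales, for the 592 windows with at least 25 reads in fog-2 males; counts below 3 reads are drawn at 3. Solid lines mark equal levels as a share of all reads and dashed lines 4-fold lower. Of the 9 kept windows, the 8 with at least 25 reads in fog-2 males are coloured; relative to abundant non-G ends all spermatid values would lie 2.98 higher on the log2 scale.

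The next question was whether 22G-RNAs, the secondary class made by RNA-dependent RNA polymerases, differ in the mutant. Their total was similar, 27.5% of reads in fog-2 males and 29.4% in mutant males (ratio 1.07, 1.07 to 1.07). Of 4744 windows compared, 121 were at least 4-fold lower in mutant males and 261 at least 4-fold higher. The median log2 ratio of all windows was -0.17.

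In the median window with at least 25 26G reads in fog-2 males, 22G-RNAs were lower in mutant males, while their sum was not. Windows with fewer 26G reads had medians near the -0.17 of all windows, at -0.18 (above 0 and under 5 reads) and -0.26 (5 to under 25). The 197 26G windows had a median log2 ratio of -1.28, below all 10000 random lists (-0.51 to -0.07), and 60 of them (30.5%) were at least 4-fold lower against 1.34% of the other windows; 12 were at least 4-fold higher. The 197 windows include 8 of the 9 kept ones and windows at the end of chromosome I. Without that end and the mitochondrial genome the median was -1.37. Summed, the 22G level of the 197 windows was 1.93 times that in fog-2 males. That of the 573 windows, which leave out the kept ones and the end of chromosome I, was 0.999 times. In the same 197 windows the median was -0.36 for G reads of 21 nt, -0.88 for 22 nt and -1.38 for 23 nt, each below all random lists matched on the reads counted. At 22 nt exactly 29 of them (14.7%, 10.1 to 20.5%) were at least 4-fold lower, against 1.58% of the other windows.

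These medians depended on which windows and which 5' ends were counted. Where 25 reads of 22 nt exactly were asked for, 81 windows were left, and their median was -0.24, within the range of random lists, and the same 81 windows had a median of -0.10 at 21 to 23 nt. The 34 windows with 25 reads of 21 nt had a median of 0.43, and the 56 with 25 reads of 23 nt one of -0.08. In the 197 windows, 22-nt reads at 5' ends shared with a 26G read had a median of -0.62, below all random lists (-0.30 to 0.12), and those at other 5' ends a median of -0.12, within their range (-0.29 to 0.12). The 34 windows with at least 25 reads at shared 5' ends had a median of 0.54. Sums, in which windows weigh by their reads, differed in direction from the medians of the 197 windows. Over these windows, kept ones and the end of chromosome I included, G reads of 21, 22 and 23 nt were 1.86, 2.39 and 1.34 times the fog-2 male level. Over the 573 windows, which leave these out, G reads of 26, 25 and 24 nt were 25.5-fold, 31.8-fold and 12.25-fold lower. Those of 23 nt were 1.75-fold lower, so that the direction of the 23-nt sum depended on the windows included. Those of 21 nt were 1.17 times the fog-2 male level (1.11 to 1.24). Those of 22 nt were 1.23 times the fog-2 male level (1.19 to 1.27), 1.01 times at shared 5' ends (0.961 to 1.07) and 1.40 times at other 5' ends (1.34 to 1.46).

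**Figure D3:**
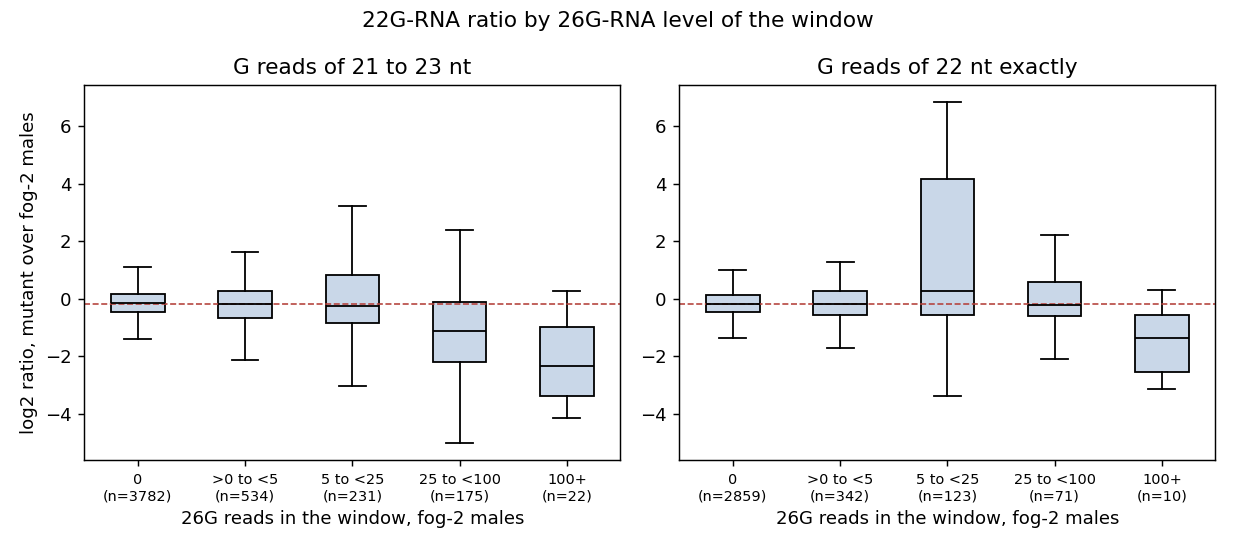
Log2 ratio of G reads, mutant over fog-2 males (y axis), for windows grouped by their 26G reads in fog-2 males (x axis), with reads of 21 to 23 nt (left) and 22 nt exactly (right). Boxes span the quartiles with the median, whiskers reach 1.5 times the box height, points beyond are not drawn, and the dashed line is the median of all windows. At 25 to under 100 26G reads the median is -1.12 on the left (175 windows) and -0.20 on the right (71 windows), and at 100 or more it is -2.35 (22 windows) and -1.34 (10 windows); each panel shows the windows with enough reads of its own length.

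Windows with fewer 22G-RNAs in mutant males included some with no 26G-RNA. On the minus strand of III, 10086001 to 10087000 held 393 22G reads in fog-2 males and 38 in mutant males, 9.51-fold lower (6.81 to 13.6), with no 26G read in any library; at 22 nt exactly it held 282 and 30. On the plus strand of IV, 3398001 to 3399000 held 106.5 and 6 reads (16.3-fold lower, 7.22 to 45.3), again without 26G-RNAs. The window with the largest difference, 2388001 to 2389000 on the plus strand of IV, held 141 and 4 22G reads (32.4-fold lower, 12.4 to 121) and lost its 26G-RNAs as well, 44 against 1. Of the 121 lower windows, 60 were 26G windows. At 22 nt exactly 41 of the 121 could be compared and 38 were at least 4-fold lower. Reads of 22 nt are part of those that made the call, so this is no independent check. Of all 43 windows at least 4-fold lower at 22 nt exactly, 8 were 26G windows.

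Windows with more 22G-RNAs in mutant males formed 125 loci of adjoining windows. At 22 nt exactly, 220 of the 261 windows could be compared and all 220 were at least 4-fold higher, although these reads are part of those that made the call. The locus with the largest gain lay on the minus strand of X, 9070001 to 9074000, with 399 reads in fog-2 males and 20635 in mutant males (56.2-fold higher, 50.9 to 62.3). The plus strand of II at 3302001 to 3318000 held 397 and 7896 reads (21.6-fold, 19.6 to 23.99), and the minus strand of IV at 8597001 to 8599000 held 171.5 and 7154.5 (45.4-fold, 38.9 to 52.9). Among single windows, 19851001 to 19852000 on the plus strand of V held 3 and 542 reads (196-fold, 66.9 to 956). On the plus strand of X, 1973001 to 1974000 held 0 and 307 reads, at least 111-fold higher at a floor of 3 reads. These loci had few 22G-RNAs in spermatids: 27 of the 261 windows held at least 25 spermatid 22G reads, against 3200 of all 4744. The rule that chose the 261 favours windows low in fog-2 males. They were not matched on that level, so this contrast is not independent of the choice.

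Of the 9 windows that kept 26G-RNAs, 7 were among those at least 4-fold higher in 22G reads and 1 was at least 4-fold lower. Summed, their 22G reads were 1605 in fog-2 males and 16373 in mutant males, 11.09-fold higher, and those of 22 nt exactly were 10.7-fold higher (10.1 to 11.4). On the minus strand of V, 20379001 to 20380000 had 91 26G reads in fog-2 males, 150 in mutant males and 3 in spermatids. On the minus strand of IV, 3897001 to 3898000 held 12 22G reads in fog-2 males and 1364 in mutant males (123-fold higher, 70.5 to 240), beside 17 and 27 26G reads.

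Chromosome X stood apart in 22G-RNAs of mutant males. Its 22G level was 1.87 times that of fog-2 males (1.84 to 1.89), while each autosome lay between 1.00 and 1.04 times. Of 415 X windows, 72 (17.3%) were at least 4-fold higher, against 189 of 4321 autosomal windows (4.37%). The median X window was near the autosomal one, at -0.05 against -0.18. Without the 5 X windows of largest gain the X ratio was 1.25, and without 20 it was 1.11; autosomes without the 100 windows of largest gain had a ratio of 0.911.

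**Figure D4:**
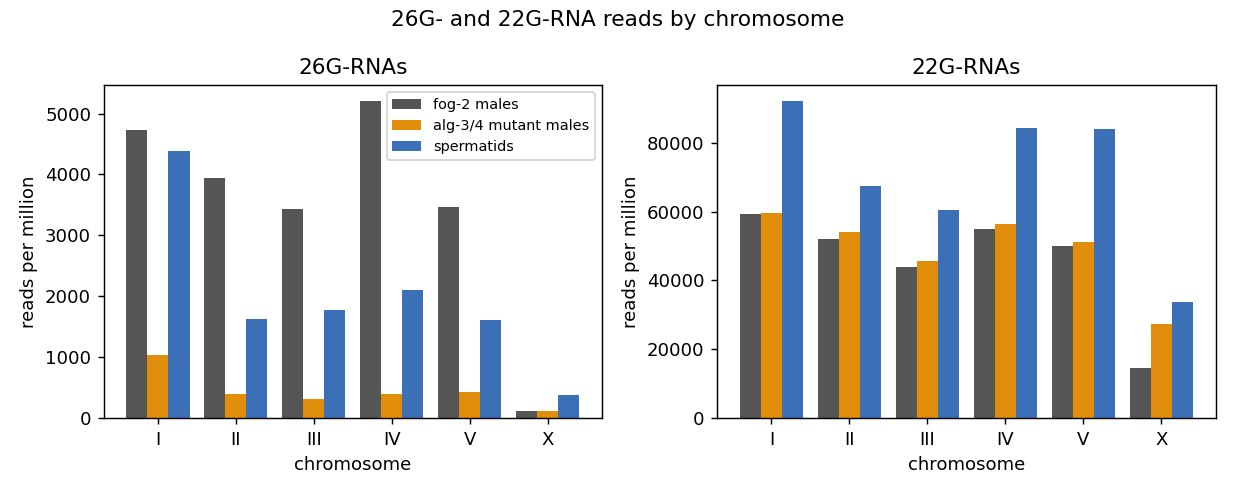
Reads scaled to the total of each library (y axis) by chromosome (x axis) for 26G-RNAs (left) and 22G-RNAs (right). On X, 26G-RNAs are scarce in fog-2 males (0.585% of the class), and 22G-RNAs in mutant males are 1.87 times the fog-2 male level; relative to abundant non-G ends all spermatid bars would be 2.98 higher on the log2 scale, which puts 26G-RNAs of spermatids above those of fog-2 males.

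Reads of 21 nt starting with U, the form of C. elegans piRNAs, were not lower in mutant males. They made up 15.4% of reads in fog-2 males and 17.9% in mutant males (ratio 1.16, 1.16 to 1.17). Outside abundant ends, the end of chromosome I and the mitochondrial genome they made up 7.19% and 9.26% (ratio 1.29), and 96.1% and 96.6% of these lay on chromosome IV, the chromosome that carries most piRNA genes. The 59 abundant non-G ends, 47 of which began with U, took 45.5% and 41.5% of reads, and their median ratio was 0.876. In mutant males 0 were at least 4-fold lower and 1 was at least 4-fold higher. That end, at 6665557 on the minus strand of V, held 629 reads in fog-2 males and 18208 in mutant males (31.5-fold higher, 29.1 to 34.1). The most abundant of the 59 ends, at 3233310 on the plus strand of IV (22 nt), held 233471 reads in fog-2 males and 183557 in mutant males. It was followed by an end at 8865214 on the minus strand of III (23 nt), with 210493 and 152818 reads.

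The second comparison asked which of these small RNAs are present in spermatids. 26G-RNAs were found there at 1.25% of reads (1.24 to 1.26%, 38733 reads), 1.68-fold below fog-2 males as a share of all reads (ratio 0.597, 0.589 to 0.604) but 4.702 times their level relative to abundant non-G ends. Those ends took 6.01% of spermatid reads against 45.5% in fog-2 males. Scaling to them raises every spermatid ratio by 2.98 on the log2 scale. Leaving the end of chromosome I and the mitochondrial genome out of the scaling total raises it by 0.26, while the class reads compared still include those regions. Counted as 25 to 27 nt, the 26G ratio was 0.925. Longer reads of all kinds were also more frequent in spermatids: reads of 26 nt with another first base took 2.15% and reads of 27 nt and longer 5.85%, against 0.352% and 0.230% in fog-2 males. Of 26-nt reads 36.8% began with G in spermatids, against 85.6% in fog-2 males. Mitochondrial reads were 4.78% of spermatid 26G reads, against 0.135% in fog-2 males. The window 15065001 to 15066000 at the end of chromosome I held 1738 and 153 26G reads. The spermatid 26G level thus includes reads of those regions.

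The 26G loci of spermatids were mostly those of fog-2 males. Outside the end of chromosome I and the mitochondrial genome, 198 windows held at least 25 26G reads in spermatids, and 163 of them also did in fog-2 males. Of the 592 fog-2 male windows, 564 held at least 3 26G reads in spermatids. As a share of all reads 222 were at least 4-fold lower and 9 at least 4-fold higher, with a median log2 ratio of -1.64. Choosing windows by fog-2 male reads alone favours lower values in spermatids. The 592 windows also include 11 at the end of chromosome I, of which 15065001 to 15066000 was 9.62-fold higher. The minus-strand window 11906001 to 11907000 of II held 330 reads in fog-2 males and 182 in spermatids, and 4059001 to 4060000 on the plus strand of III held 135 in both. The 6 windows with most 26G reads in spermatids all lay at the end of chromosome I or in the mitochondrial genome. Outside these, the first was 14477001 to 14478000 on the plus strand of X, with 1 read in fog-2 males and 187 in spermatids, none from sequences with a single match.

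22G-RNAs took the largest share of the spermatid library. They made up 42.4% of reads, 1.54 times the share in fog-2 males (1.53 to 1.54). Of 6311 windows compared, 1341 were at least 4-fold higher in spermatids and 650 at least 4-fold lower, around a median log2 ratio of 0.78. Among nuclear chromosomes X was highest, with a median of 1.51 against 0.70 on autosomes. Of its windows 41.5% were at least 4-fold higher, against 18.9% on autosomes. In mutant males, by contrast, the median X window was near the autosomal one (-0.05 against -0.18). Levels were not adjusted for the number of X chromosomes of the animals. The 14 mitochondrial windows had a median of 2.36. The 264 26G windows among those compared had a median of 0.04, just below the lowest of the random lists (0.04). At 22 nt exactly it was 0.28 for 96 windows, within the range of random lists (0.07 to 1.38). Scaled to abundant ends, 4989 windows were at least 4-fold higher and 21 at least 4-fold lower.

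Windows on both sides were 50-fold or more apart. On the plus strand of I, 5271001 to 5272000 held 377.5 22G reads in fog-2 males and 3 in spermatids (149-fold lower, 50.5 to 724). On the plus strand of III, 1822001 to 1823000 held 6 and 502 reads (70.9-fold higher, 32.3 to 194). On the minus strand of V, 17570001 to 17571000 held 372.5 and 4.5 reads, and 17572001 to 17573000 held 12 and 835.5 (59.0-fold higher, 33.6 to 115). The window 3161001 to 3162000 on the minus strand of X held 0 and 289 reads, at least 81.6-fold higher at a floor of 3 reads.

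Reads of 21 nt starting with U took 7.67% of spermatid reads, a ratio of 0.498 (0.496 to 0.501) to fog-2 males as a share of all reads and of 3.93 relative to abundant non-G ends. Outside abundant ends, the end of chromosome I and the mitochondrial genome the ratio was 0.831, and 86.7% of the reads lay on chromosome IV. Among the 59 abundant non-G ends, 42 were at least 4-fold lower in spermatids and 3 at least 4-fold higher, with a median ratio of 0.0904. The abundant end at 3233310 on the plus strand of IV was 8.72-fold lower in spermatids, and that at 12519244 on the plus strand of II was 1.67-fold lower.

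The positions of other small RNAs around 26G-RNAs were examined in all 3 libraries. On the opposite strand, 5' ends of reads of 17 to 24 nt were concentrated 22 nt downstream of the 26G 5' end. In fog-2 males 10.2% of 17678 26G 5' ends had such a partner (9.80 to 10.7%), against a median of 0.786% at other distances. In mutant males 6.21% of 2704 ends did, against a median of 0.444%, and in spermatids 5.02% of 10925, against 1.199%. The partner reads, for this count those of 17 to 30 nt, were mostly 22 nt long in fog-2 males (64.5%, 2493 reads) and in spermatids (55.01%, 450 reads). In mutant males 44.7% were 21 nt (139 reads) and 33.1% were 22 nt (103 reads), so that these shares rest on few reads. 26G 5' ends on the same strand were most often 23 nt apart, in 4.54% of ends in fog-2 males against a median of 2.08%.

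**Figure D5:**
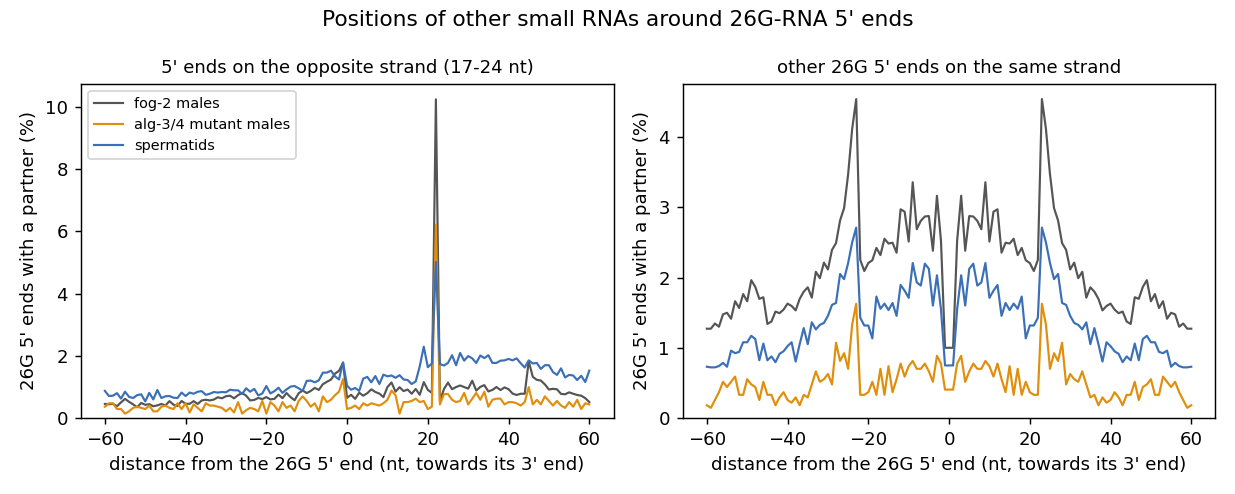
Percent of 26G 5' ends (y axis) with another 5' end at each distance (x axis, nt), for reads of 17 to 24 nt on the opposite strand (left) and other 26G-RNAs on the same strand (right), 1 line per library. The peak on the left is at 22 nt in each library (10.2%, 6.21% and 5.02%), and those on the right at 23 nt.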

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

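In spermatids 3 sets of reads stood higher than in fog-2 males, and for those of 27 nt and longer these shares were given above. The comparisons were mainly of 26G, 22G and 21U reads and abundant ends. Reads of these classes within the mitochondrial genome and the end of chromosome I did enter the class levels and windows. None of these values was tested, and no explanation was weighed. Mitochondrial reads took 4.57% of the spermatid library, 0.556% of the fog-2 male library and 0.377% of the mutant library. Of the spermatid mitochondrial reads 99.9% lay on the plus strand of the files and 11.5% started with G. Reads at the end of chromosome I took 15.3% of the spermatid library, 3.58% of the fog-2 male library and 5.01% of the mutant library. Reads of 27 nt and longer that did not cross a junction took 5.85% of the spermatid library, 0.230% of the fog-2 male library and 0.705% of the mutant library.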

How the results depend on the processing

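Beyond the alternatives on class definition, distinct sequences and single matches of the class levels, all were chosen after seeing the data. Scaling per miRNA read, coding sequence alone and all gene-level results were not run, since no annotation of the files' build was at hand. No paired analysis was possible because each group had 1 library, and no library could be left out. Of 76 alternatives to 12 results, 37 stayed within the counting interval or within 1.5 times of the count, 37 moved beyond it with no change of direction, and 2 reversed. The cause of each move was not tested, except that other read minimums and folds admit more or fewer windows by construction.

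The mutant 26G ratio (0.130) was 0.145 scaled to abundant ends, 0.114 with single matches, 0.187 at 25 to 27 nt and 0.190 by distinct sequences. The spermatid 26G ratio (0.597) was 0.713 without the end of chromosome I and mitochondrial reads in the scaling, 0.538 with single matches, 0.925 at 25 to 27 nt, 0.676 by distinct sequences, and reversed to 4.702 scaled to abundant ends. The mutant 22G ratio was 1.08 and 1.19 under those scalings and 1.05 at 22 nt exactly. The spermatid one was 1.84, 12.1, 1.48 with single matches and 1.41 at 22 nt exactly. The mutant 21U ratio was 1.18, 1.29 and, outside abundant ends, 1.29; the spermatid one was 0.596, 3.93 (reversed) and 0.831.

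26G windows lower in mutant males numbered 985 at a minimum of 10 reads and 43 at 100, against 565. For 22G windows, minimums of 10 and 100 gave 322 and 15 lower and 417 and 152 higher in mutant males, and 1796 and 112 lower in spermatids; 100 gave 527 higher there. At 2-fold, 482 were lower and 379 higher in mutant males (121 and 261 at 4-fold), and 1313 lower and 2831 higher in spermatids. Scaled to abundant ends, 21 were lower and 4989 higher in spermatids. At 22 nt exactly, 43 were lower in mutant males. The median log2 22G ratio of 26G windows (-1.28) was -0.24 at 22 nt exactly, where 81 of the 197 windows could be compared (-0.10 for the same 81 at 21 to 23 nt, -0.88 for all 197 at 22 nt), and -2.89 at a minimum of 100 reads.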

Other observations

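All tests in this part were run on the data in which the patterns were seen. Those on the label and the yield and depth of the mutant library, on scaling of chromosome X, on the matches, reads and spermatid level of the kept 26G windows, and on 22G reads by length were chosen after the result was seen. The tests on 22G reads by length, and their bounds, were also revised after a first set (the median of the 81 windows compared at 22 nt, -0.24, and the sum at other 5' ends, 1.40), because that set mixed read length with the choice of windows; the bound on the spermatid level was later extended to both scalings. Those on structural RNA and on the length tail in the kept windows, and on matches and loci of chromosome X, were written before their values were known.

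Reads across exon junctions were mostly of the G-starting kind in each library: 85.7% of 39620 junction reads in fog-2 males, 80.3% of 32518 in mutant males and 83.7% of 69092 in spermatids began with G. Windows with 5 to under 25 26G reads in fog-2 males had the highest rate of 22G gains in mutant males of the 5 levels compared. Of 231 such windows 21.6% were at least 4-fold higher, against 3.46% of 3782 windows with no 26G read and 0% of 22 windows with 100 or more. At 22 nt exactly, 39.8% of 123 such windows were at least 4-fold higher, against 3.67% of 2859 windows with no 26G read. With 100 or more 26G reads it was 0% of 10 windows. The minimum of 25 reads left fewer windows of this kind at 22 nt than at 21 to 23 nt, 123 against 231. The rates of 39.8% and 21.6% thus rest on different sets of windows, and their difference does not show a stronger pattern at 22 nt.

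The 26G-RNAs were 7.70-fold lower in the mutant library, and the source name and antibody tag call that library a CSR-1 immunoprecipitate. CSR-1 carries 22G-RNAs, so an immunoprecipitate would hold little of other classes; abundant non-G ends and 21U-RNAs together kept 0.963 of their fog-2 male share, which argues against those labels. Reads of 26 nt with another first base were 1.28 times the fog-2 male level, which argues against a poor yield of long reads, and the mutant library held 0.919 times the reads of fog-2 males, too many for depth to be the cause. What remains is the genotype or an unknown difference between 2 single libraries, which the design cannot separate. The loss of alg-3 and alg-4 is thus a hypothesis consistent with a ratio that stayed between 0.114 and 0.190 under the alternatives.

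The 9 windows that kept 26G-RNAs, although 1 was 2.81-fold lower, may belong to a second 26G class that does not need ALG-3 and ALG-4. Of their 26-nt reads in the mutant library 98.9% began with G, against 21.98% at the end of chromosome I, which argues against structural RNA fragments. The rule that chose the windows asked for G reads in that library, which favours a high share. Of their 26G reads 99.96% had a single match. They held a median of 50 26G reads in fog-2 males, against 40 for all 26G windows, but the rule that chose them set a minimum of reads, so that this comparison decides nothing. Their 26-nt G reads were 3.92 times their 25-nt G reads in the mutant library, which argues against a length tail of the abundant 22G-RNAs there. Their spermatid level was 0.0542 of that in fog-2 males as a share of all reads but 0.428 relative to abundant non-G ends, so that a class outside sperm stays open, although under either scaling the ratio was 0.143 of that of the other 26G windows; the ERGO-1 class of 26G-RNAs is a candidate explanation, which could not be tested without gene names.

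The lower 22G level of the median window with at least 25 26G reads in fog-2 males may in part reflect shortened 26G-RNAs counted as 22G-RNAs. The sum over the 573 windows other than the kept ones was 0.999 times the fog-2 male level. Shortened reads of 23 nt are argued against as the whole cause, since 14.7% of the 197 windows were at least 4-fold lower at 22 nt exactly, against 1.58% of others. At 5' ends shared with 26G-RNAs the median log2 ratio of 22-nt reads was -0.62, below all random lists, but their sum was 1.01 times the fog-2 male level and the median of the 34 windows with 25 such reads was 0.54, and 22G-RNAs made at those ends would lower the median as well, so that the 2 cannot be told apart. At other 5' ends the median was -0.12, within the range of random lists, and the sum was 1.40 times the fog-2 male level, which leaves open whether 22G-RNAs were lower in most windows there.

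The 22G ratio of chromosome X in mutant males was 1.92 with sequences of a single match, 1.82 relative to autosomes, and 1.11 without the 20 X windows of largest gain.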
